A study of Mus musculus with 6 samples.

How the data were processed

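Gene expression in mouse muscle was measured by RNA sequencing in 6 libraries, 3 from mice treated with click and 3 from mice treated with EDC. Per the labels' protocols, RNA was extracted with a column kit and libraries were made from 1 µg of total RNA with a SMARTer mRNA kit. The deposited table holds read counts per gene, as whole numbers that were not normalised, with a column for each library. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, the annotation and the use of strand are not given in the sources used here, so reads from genes that overlap on opposite strands cannot be told apart. Reads that match several near-identical genes appear to be counted at each of them, because the nuclear copy Gm28661 held 1.00 times the reads of mt-Co2 in every library. Values of mitochondrially encoded genes with nuclear copies are uncertain for that reason.

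The table had 55335 lines. On 3225 of them no gene symbol was given, and these held 0.0631% to 0.0996% of the reads of a library. They were left out of library sizes and tests. For 80 symbols on 2 lines, the line with more reads took the plain name. The remaining 52110 lines were used. They include 26 lines whose symbol had been turned into a date, so that the gene is not known; 22 of these were tested and 1 is among the DESeq2 calls, and none is named here. Of 52030 distinct symbols, 47745 were in the GENCODE M21 annotation of the same build, and 97.8% of the 15797 genes tested were. Coordinates come from that annotation, start and end counted from 1. The table had no column of per-sample values without a sample.

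Groups and replicate numbers were taken from the labels. The series design names 3 mice per group, so each library was treated as a separate animal. Neither group is labelled as untreated, and directions are given as click relative to EDC. No label gives a batch, a day or the sex of a mouse. The counts of each pair of libraries differed by 61.8 to 470 times the sampling variance per gene, so no pair agreed within sampling noise.

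The main comparison used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM factors, the default expression filter by group, robust dispersion and no covariate. P-values were adjusted by Benjamini-Hochberg over 15797 genes, with a threshold of 0.05. The standard error of a log2 fold change is the change divided by the square root of its F statistic. Levels are in CPM, the reads of a gene relative to all reads of its library, scaled by the TMM factors and computed here from the deposited counts. Group values are mean ± SD over n = 3 libraries.

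Gene lists were compared with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes. The test sets the members of a list against the other genes. Its p-values were adjusted over the 40 lists with at least 5 measured members. It was repeated with an estimated correlation and on ranks, and fry was run for its directional and mixed p. A list score is the mean over members of log2 CPM, each centred on its mean over the 6 libraries. Scores were compared by an exact two-sided permutation test, for which 0.1 is the smallest p that 3 against 3 libraries allow. Lists have members in common, so their results are not independent. Of the list members, 4 symbols were not found in the table.

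The 41 lists, the tests and the rule for named genes were fixed before the data were examined. The lists cover fast fibre, slow fibre, regeneration, denervation, collagen and matrix, matrix remodelling, myofibroblast, fibroblast, macrophage, alternatively activated macrophage, giant cell and lysosomal, neutrophil, mast cell and eosinophil, T and NK cell, B and plasma cell, antigen presentation, cytokine, NF-kB, interferon, complement, endothelial, pericyte and smooth muscle, angiogenesis, adipocyte, Schwann cell and nerve, skin, tendon and bone, erythroid, nuclear respiratory chain, mitochondrially encoded, glycolysis, fatty acid oxidation, cell cycle, oxidative stress, heat shock, immediate early, p53, clock, glucocorticoid, ribosomal protein and sex-linked genes. The rule names genes past the threshold with a mean log2 CPM of at least 1 whose groups do not overlap, up to 8 per direction, leaving out predicted genes. It also names up to 3 members past the threshold from each list, or the member with the smallest p where none passes, and the 5 genes with the most reads. Chosen after their values were seen were Mb, Myh7, Myl2, Sln, Col3a1, Col1a2, Ctsk, Mmp9, Mmp12, Mmp13, Lyz2, Cd68, S100a9, Retnlg, Il7r, Trbc2, Ccl9, C1qb, Atp5a1, Rplp0, Cd79a, Ms4a1, Mapk3, Ypel3, mt-Atp6 and Gm10925, and the genes named only in the closing section. Some genes that the rule names are not reported here.

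Alternatives were DESeq2 size factors, upper-quartile factors and library totals alone in place of TMM, no low-count filter, a filter at a mean of 50 reads, the DESeq2 1.42.0 Wald test, limma-voom, edgeR without robust dispersion, library sizes without mitochondrial, haemoglobin and the 20 most abundant genes, the replicate number as a block, a log2 fold threshold of 1, and leaving out each library in turn. Sex read from Xist and Y-linked reads as a covariate, male libraries alone, and the mt-Atp6 read class as a covariate were added after seeing the data. Adjusted p-values that DESeq2 did not give (24 genes) were left out.

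The tests were checked on simulated counts for this comparison, drawn for 15439 genes with 50 genes changed at each of 4 sizes. The edgeR test recovered 8% of genes changed 2-fold, 60% changed 4-fold, 92% changed 8-fold and 94% changed 16-fold, with 13 false calls among 140. The DESeq2 test recovered 7, 36, 48 and 49 of the 50 genes at those sizes, with 48 false calls among 188. Changes of 2-fold were therefore mostly below what this design can call. Libraries held 34472421 to 39305779 reads, so counting error is small for abundant genes, and the spread between libraries sets the precision. The labels mention no molecular identifiers, so reads may not be independent molecules.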

Results

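RNA from muscle of c57b6l wild-type mice was sequenced in 6 libraries, 3 from mice given the agent labelled click and 3 from mice given the agent labelled EDC. The labels name the strain, the tissue and the agent only. Reads in named and unnamed genes summed to 39305779, 35689994 and 36086701 in click replicates 1, 2 and 3, and to 36088456, 34472421 and 38094826 in EDC replicates 1, 2 and 3. The 5 genes with the most reads were the mitochondrially encoded mt-Co1 and mt-Cytb, the fast fibre genes Myh4 and Tnnt3, and the skeletal actin gene Acta1.

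The libraries differed in composition. Mitochondrially encoded genes took 30.2%, 27.0% and 18.9% of the reads in click replicates 1 to 3 and 14.8%, 17.8% and 16.8% in the EDC replicates. Genes detected numbered 18628, 18844 and 20655 in click and 20944, 19713 and 21380 in EDC. Reads of Xist, which is transcribed from the inactive X chromosome of females, were found in replicate 1 of each group (8755 and 11813 reads) and numbered 0 in the other 4 libraries. Reads of the Y-linked gene Ddx3y numbered 1857 to 2379 in those 4 libraries and 0 in the others. Each group thus held 1 library with female and 2 with male reads. The first principal component of log2 CPM took 47.9% of the variance, with click replicate 2 at one end (-117) and EDC replicate 3 at the other (74.6). The ratio of mt-Atp6 reads to reads of its nuclear copy Gm10925 was 0.927 to 0.937 in click replicate 2 and EDC replicates 1 and 3 and 0.162 to 0.166 in the others, and is called the mt-Atp6 read class.

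The edgeR test called 1 gene as different between click and EDC muscle, Gdpd3. It rose 41.5-fold in click, a log2 fold change of 5.37 (SE 0.40, edgeR adjusted p = 0.0404), and its level was above that of every EDC library in 3 of 3 click libraries. Gdpd3 encodes a lysophospholipase D of the glycerophosphodiester phosphodiesterase family. Its level was 20.7 ± 7.75 CPM in click and 0.497 ± 0.0987 CPM in EDC (SD, n = 3). The protein-coding gene (ENSMUSG00000030703.8) lies on chromosome 7 from 126766334 to 126775649 on the plus strand of mm10. Its neighbours on the same strand gave a log2 fold change of -0.55 for Mapk3 (edgeR adjusted p = 0.395) and -0.13 for Ypel3 (edgeR adjusted p = 0.867).

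The Gdpd3 call was near the threshold, and its log2 fold change lay between 4.81 and 5.65 in every alternative run. Its edgeR adjusted p was 0.125 without click replicate 2, 0.372 without EDC replicate 1, 0.234 without EDC replicate 2 and 0.126 without EDC replicate 3. The call was lost too with the replicate number as a block (edgeR adjusted p = 0.0877) and with sex read from the counts as a covariate (0.107). It was also lost in male libraries alone (0.231) and with mt-Atp6 read class as a covariate (0.254). No gene was lower in click by the edgeR test. At an unadjusted p under 0.05, edgeR gave 2404 genes (1141 higher, 1263 lower) where 790 are the chance number if genes are independent, and the split of click replicates 1 and 2 with EDC replicate 2 from the other 3 libraries gave 2517. In 3509 genes, 22.2% of those tested, the 3 click values did not overlap the 3 EDC values, where chance gives 10%. The DESeq2 Wald test called 606 genes, 247 higher and 359 lower in click, and limma-voom called 0, with 2602 at an unadjusted p under 0.05.

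Groups of related genes tended to lie higher or lower together, but the calls depended on the correlation assumed between genes. Of the 40 lists tested, camera called 22, 8 lying higher and 14 lower in click. The split of click replicates 1 and 2 with EDC replicate 2 from the rest gave 24 called lists. The estimated correlation within the 22 lists was 0.0585 to 0.866, above the preset 0.01. None was called with an estimated correlation, where the adjusted p of these 22 lists was 0.511 to 0.592 and no list had an unadjusted p under 0.05. The directional test of fry called 0 (6 at an unadjusted p under 0.05), and its mixed test called 7. Of these 7, only the pericyte and smooth muscle list is among the 22. The others were the alternatively activated macrophage, mast cell and eosinophil, denervation, skin, glucocorticoid and clock lists. Scores of the groups did not overlap in 15 of the 40 lists, 12 of them among those called by camera, where chance gives 4. Of 636 genes in the lists, 0 passed edgeR's threshold over all genes, 189 had an unadjusted edgeR p under 0.05 and 86 were called by DESeq2. Adjusted over the list alone, 68 members passed summed over the lists, where a gene in 2 lists can count in each. The plot of list scores gives each library.

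**Figure D1:**
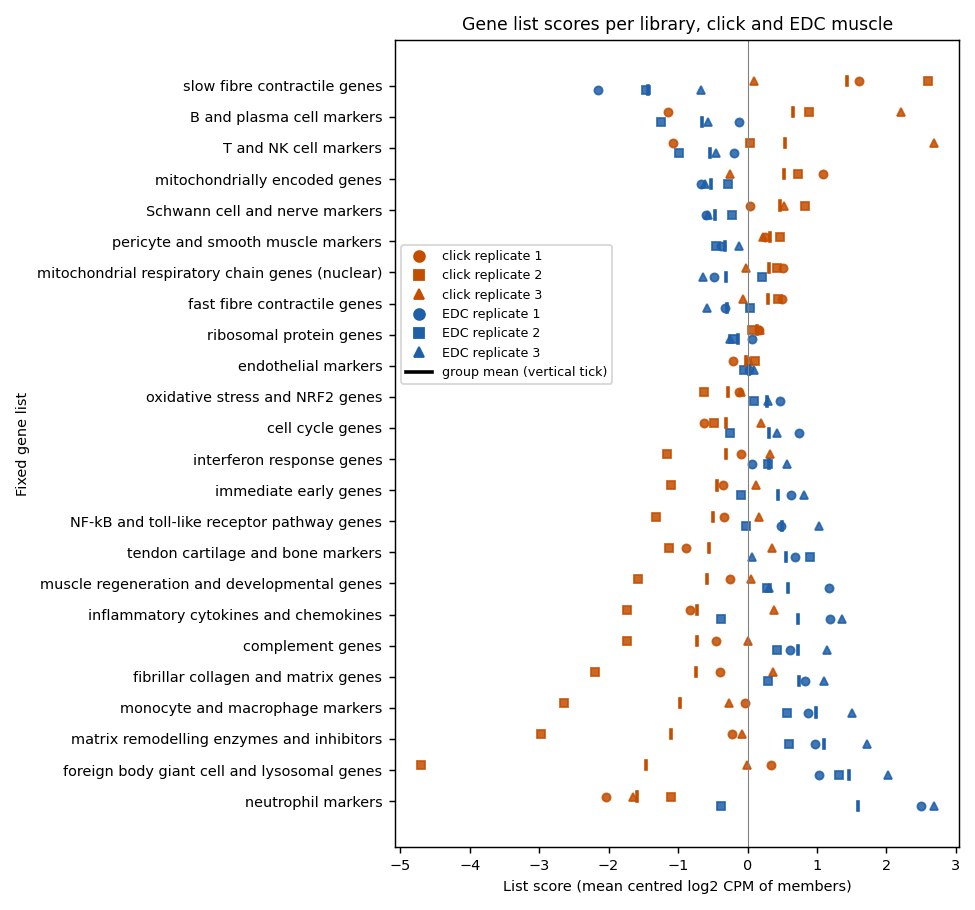
Gene list scores per library for the 22 lists called by camera and for the endothelial and the B and plasma cell lists. The x axis is the mean over members of log2 CPM centred on each gene's mean over 6 libraries, the y axis the list, the points are libraries (orange click, blue EDC) and vertical ticks are group means; click replicate 2 lies at -4.71 for giant cell and lysosomal genes while the other click libraries lie at 0.34 and 0.00.

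Contractile genes of slow fibres lay higher in click muscle. The median log2 fold change of the 12 measured members was 2.90, 11 of them were higher, and 10 passed adjusted over the list alone. Myh7, the slow myosin heavy chain, stood at 983 ± 795 CPM in click and 23.5 ± 29.8 in EDC (log2 fold change 5.39, SE 1.41). Myl2, the slow regulatory light chain, stood at 732 ± 589 against 17.1 ± 19.1 CPM (5.42, SE 1.49). Values were 3.93 (SE 0.79) for Tnnc1, the slow troponin C, and 1.51 (SE 0.44) for myoglobin, Mb. The camera adjusted p was 1.38e-06, and the adjusted p was 0.511 with an estimated correlation. The 3 click scores (1.60, 2.59 and 0.09) lay above the 3 EDC scores (-2.16, -1.46 and -0.67), with an exact permutation p of 0.1. DESeq2 called 10 of these genes, all higher in click.

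Fast fibre genes lay higher by less, with a median of 0.56 and 13 of 14 members higher (camera adjusted p = 0.00130; adjusted p = 0.511 with an estimated correlation). None passed adjusted over the list alone, and 1 had an unadjusted edgeR p under 0.05. Myh4, the fastest myosin, was at 38907 ± 8603 against 32548 ± 8340 CPM (0.26, SE 0.35), and Tnnt3 at 23326 ± 5779 against 17185 ± 4760 (0.44, SE 0.36). Both turned negative when library totals replaced TMM factors, at -0.25 and -0.069, and the list median fell to 0.061. The median was 0.33 without EDC replicate 3. Acta1 gave 0.68 (SE 0.34), and Myh2, the myosin of oxidative fast fibres, gave 1.82 (SE 0.71), with 1094 ± 485 against 310.0 ± 239 CPM.

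Genes of muscle regeneration and development lay lower, with a median of -0.93 and 13 of 16 members lower, 2 of them past the threshold adjusted over the list alone (camera adjusted p = 0.00205; adjusted p = 0.511 with an estimated correlation). Chrna1, an acetylcholine receptor subunit, stood at 30.0 ± 3.66 CPM in click and 56.1 ± 11.8 in EDC (-0.90, SE 0.22). Another subunit gene, Chrnd, gave -1.86 (SE 0.42). It belongs to the denervation and atrophy list, which was not called (median -0.44, camera adjusted p = 0.111) and held 2 members higher and 2 lower adjusted over the list alone. Sln, the sarcolipin gene, whose product inhibits the calcium pump, stood at 40.7 ± 15.2 against 195 ± 111 CPM (-2.26, SE 0.49).

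Macrophage genes lay lower in click, as did genes of giant cells and lysosomes. Among 21 macrophage markers 19 were lower, with a median of -1.88, and 11 passed adjusted over the list alone. Mertk, a receptor for the uptake of dying cells, gave -1.93 (SE 0.49), Lyz2, lysozyme, -1.75 (SE 0.76), and Cd68 was at 48.2 ± 43.8 against 200 ± 89.3 CPM (-2.05, SE 1.06). All 17 genes of the giant cell and lysosomal list were lower, with a median of -2.00. The cathepsin Ctsb stood at 611 ± 264 CPM in click and 1880.3 ± 905 in EDC (-1.62, SE 0.47), and Ctsk gave -2.14 (SE 1.20). Mmp12, the macrophage elastase, stood at 119.6 ± 104 against 398 ± 266 CPM and was at 0 reads in click replicate 2. Camera gave an adjusted p of 8.49e-07 for macrophage and 4.27e-06 for giant cell genes, and the adjusted p was 0.511 with an estimated correlation for both. With mt-Atp6 read class as a covariate the giant cell median moved to -3.94. No giant cell gene passed adjusted over the list alone, and 5 had an unadjusted edgeR p under 0.05. The alternatively activated macrophage list was not called (median -0.81, camera adjusted p = 0.479), and its member Retnla, a secreted resistin-like protein, went the other way and passed adjusted over the list alone, at 4.39 ± 0.896 against 0.782 ± 0.124 CPM (2.48, SE 0.34).

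Genes of the extracellular matrix lay lower. All 22 collagen and matrix genes were below their EDC level, with a median of -1.15 (camera adjusted p = 7.23e-07; adjusted p = 0.511 with an estimated correlation). None passed adjusted over the list alone, and 6 had an unadjusted edgeR p under 0.05. Col3a1 gave -1.05 (SE 0.69), Col1a2 -1.34 (SE 0.61) and Fbn1, fibrillin 1, -1.08 (SE 0.36). The median was -1.86 without click replicate 3 and -1.82 with mt-Atp6 read class as a covariate. The mean score of the list in click lay -1.48 from that in EDC with all libraries, and -0.75 without click replicate 2. Remodelling enzymes and inhibitors had a median of -1.71, with 16 of 18 lower and 10 at an unadjusted edgeR p under 0.05 (camera adjusted p = 1.34e-05; adjusted p = 0.511 with an estimated correlation). Among them, Mmp8 gave -4.79 (SE 1.36), Mmp13 -4.60 (SE 1.57) and Mmp9 -1.87 (SE 1.13). Click replicate 2 had the lowest score of the 6 libraries in the macrophage, giant cell, matrix and remodelling lists.

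Neutrophil markers had the lowest median, -4.04, with all 12 members lower and 7 past the threshold adjusted over the list alone (camera adjusted p = 1.10e-05; adjusted p = 0.511 with an estimated correlation). Csf3r, the receptor for granulocyte growth factor, was at 2.64 ± 0.996 CPM in click and 17.6 ± 14.4 in EDC (-2.73, SE 0.67). S100a9, a calprotectin subunit, was at 2.71 ± 2.66 against 50.5 ± 42.1 CPM (-4.23, SE 1.33). EDC replicates 1 and 3 had scores of 2.50 and 2.68 and EDC replicate 2 had -0.39, above the click scores of -2.03, -1.11 and -1.65. EDC replicates 1 and 3 share the mt-Atp6 read class with click replicate 2, and 2 neutrophil genes followed that class in all 6 libraries. S100a9 had 158, 3183 and 3854 reads in those 3 libraries and 43, 32 and 72 in the others, and Retnlg had 16, 328 and 365 against 0, 0 and 0. With the class as a covariate the list median was -2.82 (camera adjusted p = 1.58e-06).

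**Figure D2:**
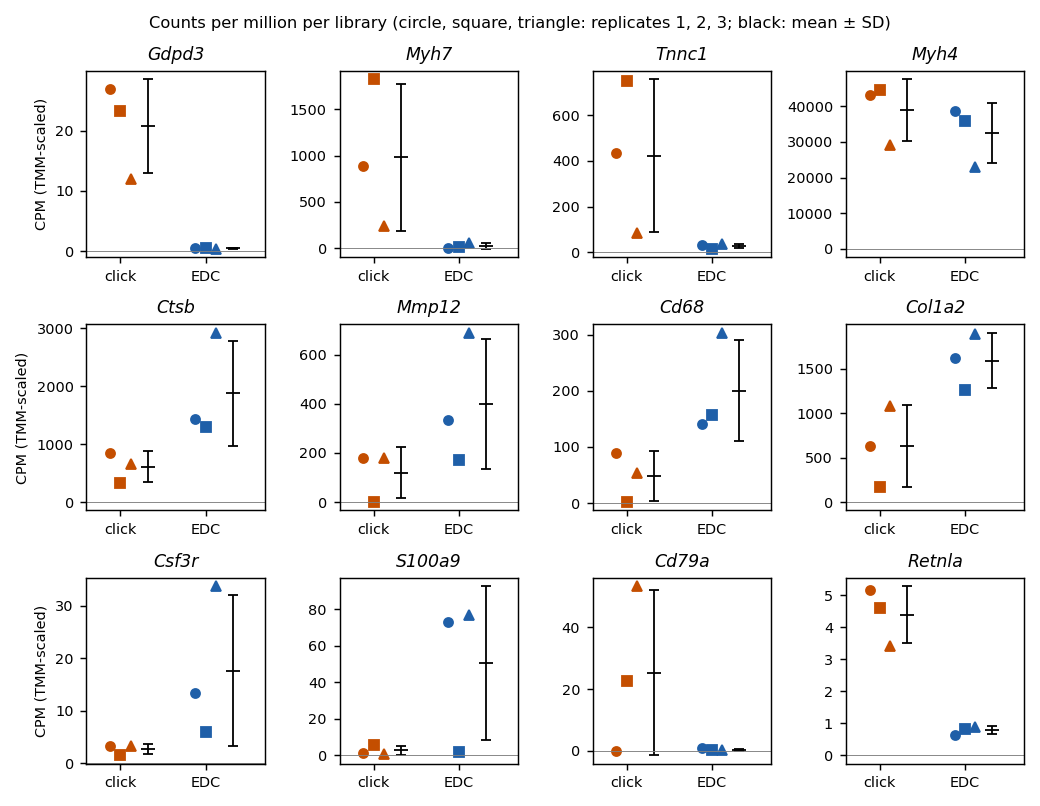
TMM-scaled CPM of 12 genes, with library values as points (orange click, blue EDC; circle, square and triangle for replicates 1, 2 and 3) and the mean ± SD of n = 3 in black. Each y axis is linear CPM; Gdpd3 lies at 20.7 ± 7.75 in click and 0.497 ± 0.0987 in EDC, while the spread of S100a9, Mmp12 and Cd79a is close to their group means.

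Inflammatory genes lay lower as well. The 22 cytokine and chemokine genes had a median of -1.66, with 20 lower and 12 at an unadjusted edgeR p under 0.05 (camera adjusted p = 3.68e-05; adjusted p = 0.511 with an estimated correlation). Csf1, the growth factor of macrophages, gave -0.94 (SE 0.24), and the chemokine Ccl9 gave -2.28 (SE 0.79). That median was -2.57 without click replicate 3 or without EDC replicate 2, and -1.03 without EDC replicate 3. Complement genes had a median of -1.19 with 14 of 15 lower (camera adjusted p = 2.23e-05; adjusted p = 0.511 with an estimated correlation), and C1qc and C1qb gave -2.02 (SE 0.62) and -1.88 (SE 0.72). Genes of the NF-kB and toll-like receptor pathway had a median of -0.77 with 21 of 21 lower (camera adjusted p = 3.89e-04; adjusted p = 0.511 with an estimated correlation), among them Cd14 at -2.54 (SE 0.82). The NF-kB median was -0.50 without click replicate 2, -1.23 without click replicate 3 and -0.51 without EDC replicate 3. Click replicate 2 had the lowest score in the cytokine, complement and NF-kB lists. Cytokine and NF-kB scores overlapped between the groups, with click replicate 3 (0.38 and 0.17) above EDC replicate 2 (-0.38 and -0.02). The exact permutation p was 0.2 for both.

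Immediate early genes had a median of -0.72 with 19 of 22 lower (camera adjusted p = 2.55e-04; adjusted p = 0.511 with an estimated correlation), and Junb, a subunit of the AP-1 factor, gave -1.53 (SE 0.42). The median was -1.18 without click replicate 3 and -1.17 with library totals alone. For interferon response genes the median was -0.42, with 20 of 27 lower (camera adjusted p = 0.00493; adjusted p = 0.574 with an estimated correlation), and Oasl2 gave -1.58 (SE 0.45). This call was lost without click replicate 2 (median -0.21, camera adjusted p = 0.223) and with library totals (camera adjusted p = 0.0525), and the median was -0.82 without click replicate 3. Cell cycle genes had a median of -0.64 with 16 of 20 lower (camera adjusted p = 0.00237; adjusted p = 0.574 with an estimated correlation), and E2f1 gave -1.31 (SE 0.36). In male libraries alone the cell cycle median was -0.14 (camera adjusted p = 0.405), and the call was lost too without click replicate 1 (-0.42, 0.0666) and without EDC replicate 1 (-0.33, 0.0557). The median was -1.01 without click replicate 3.

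Oxidative stress genes had a median of -0.38 with 14 of 18 lower and 3 past the threshold adjusted over the list alone (camera adjusted p = 0.0196; adjusted p = 0.511 with an estimated correlation). Mt1, a metal-binding metallothionein, stood at 8.60 ± 1.81 CPM in click and 20.6 ± 3.84 in EDC (-1.26, SE 0.24). Without click replicate 3 the camera adjusted p was 0.0883, and without EDC replicate 1 it was 0.0557. Tendon, cartilage and bone markers had a median of -1.01 with 9 of 12 lower (camera adjusted p = 0.0289; adjusted p = 0.511 with an estimated correlation), with Sox9, a cartilage transcription factor, at -1.45 (SE 0.46). That call was lost without EDC replicate 1 (-0.85, camera adjusted p = 0.0587), without EDC replicate 2 (-0.71, 0.0938), in male libraries alone (-0.56, 0.0964), with library totals (-1.36, 0.270) and with the filter at 50 reads (-1.01, 0.0701). The tendon median was -0.64 without click replicate 2 and -1.94 without click replicate 3.

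Mitochondrial genes lay higher in click. All 15 mitochondrially encoded genes were higher, with a median of 1.19, and 13 passed adjusted over the list alone (camera adjusted p = 7.23e-07, adjusted p = 0.511 with an estimated correlation). The list score of click replicate 3 (-0.253) lay just above that of EDC replicate 2 (-0.280). Among the 15, mt-Atp6 stood at 5626, 24568 and 2242 CPM in click replicates 1 to 3 and 8927, 2350 and 9097 in EDC. Its higher click mean thus rests on click replicate 2. The most read gene, mt-Co1, stood at 100849 ± 40017 CPM in click and 44172 ± 8168 in EDC (1.19, SE 0.42), mt-Cytb gave 1.15 (SE 0.43) and mt-Nd4l 1.54 (SE 0.41). The median was 0.77 in male libraries alone and 0.63 with library totals. All 26 nuclear genes of the respiratory chain were higher, with a median of 0.55 (camera adjusted p = 7.23e-07; adjusted p = 0.511 with an estimated correlation), 2 of them at an unadjusted edgeR p under 0.05. Cox6a2, a muscle form of a cytochrome oxidase subunit, gave 0.98 (SE 0.33) and Atp5a1 0.51 (SE 0.30). That median was 0.83 without EDC replicate 2 and 0.07 with library totals, a setting that moved the median of all genes by -0.48.

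Ribosomal protein genes had a median of 0.30 with 28 of 30 higher (camera adjusted p = 1.02e-04; adjusted p = 0.511 with an estimated correlation), and Rps2 and Rplp0 gave 0.64 (SE 0.22) and 0.55 (SE 0.22). With library totals the median turned to -0.18 and the call was lost (camera adjusted p = 0.145). Markers of Schwann cells and nerve had a median of 1.32 with 11 of 14 higher and 3 past the threshold adjusted over the list alone (camera adjusted p = 0.00617; adjusted p = 0.511 with an estimated correlation). The median was 0.73 without click replicate 2 and 0.85 with library totals. Pericyte and smooth muscle markers had a median of 0.32 with 11 of 13 higher (camera adjusted p = 0.00567; adjusted p = 0.511 with an estimated correlation), which turned to -0.20 with library totals. Myh11, the smooth muscle myosin, stood at 38.9 ± 8.63 CPM in click and 13.4 ± 1.89 in EDC (1.53, SE 0.23) and passed adjusted over the list alone. The pericyte median was 0.12 without click replicate 2 and 0.21 without EDC replicate 3.

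Lymphocyte genes differed among the click libraries. T and NK cell markers had a median of 2.62 with 17 of 20 higher, 9 members at an unadjusted edgeR p under 0.05 and none past the threshold adjusted over the list alone (camera adjusted p = 0.0236; adjusted p = 0.592 with an estimated correlation). The T cell genes Cd8b1 and Trbc2 gave 4.58 (SE 1.19) and 3.18 (SE 1.18), and Il7r, the interleukin 7 receptor, went the other way at -1.69 (SE 0.82). Scores were -1.08, 0.03 and 2.68 in click and -0.20, -0.99 and -0.45 in EDC, and the exact permutation p was 0.5. Without click replicate 3 the median was 0.40 and the call was lost (camera adjusted p = 0.678), and it was lost too without EDC replicate 2 (2.21, camera adjusted p = 0.0938) and with mt-Atp6 read class as a covariate (2.37, 0.0517). B and plasma cell markers were not called (median 1.53, camera adjusted p = 0.118), with 4 members higher and 1 lower adjusted over the list alone. Cd79a, a subunit of the B cell receptor complex, stood at 25.4 ± 26.8 CPM in click and 0.426 ± 0.328 in EDC (5.89, SE 1.74). Without click replicate 1 the B cell list was called (median 3.20, camera adjusted p = 7.93e-08) and Ms4a1 passed the edgeR test over all genes. The B cell list was called too without EDC replicate 1 (2.92, camera adjusted p = 0.00749), without EDC replicate 3 (2.82, 0.0170) and in male libraries alone (3.38, 4.39e-10).

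The other lists were not called by camera. Medians lay below 0 for myofibroblast (-0.74), fibroblast (-0.46), adipocyte (-0.55), mast cell and eosinophil (-0.77), skin (-1.19), p53 (-0.42), glucocorticoid (-0.16), antigen presentation (-0.07) and endothelial genes (-0.02). They lay above 0 for fatty acid oxidation (0.33), glycolysis (0.45), erythroid (0.18), heat shock (0.10), clock (0.17) and angiogenesis genes (0.07). The camera adjusted p ran from 0.0697 for myofibroblast to 0.902 for angiogenesis genes. Signs differed for antigen presentation, where the mean was 0.21 while the test pointed lower, and for angiogenesis, where the mean was -0.09 and the test pointed lower. Members with the smallest p of their list included Pparg, the regulator of fat cells, at -1.44 (SE 0.27), Trp63, a keratinocyte factor, at -1.19 (SE 0.26), Pdgfrb at -0.82 (SE 0.22), Ear2 at -1.86 (SE 0.45), Pgam1 at -1.35 (SE 0.39), Angptl4 at -1.55 (SE 0.52), Angpt2 at -0.89 (SE 0.23), Per2 at -1.09 (SE 0.28), Bcl2l11 at -1.28 (SE 0.35), Sesn2 at -0.98 (SE 0.36), Cd80 at -1.42 (SE 0.42), Plvap at -0.65 (SE 0.27) and Hbb-bs at 0.52 (SE 0.22). None of these 13 passed the edgeR test over all genes (adjusted p 0.298 to 0.325). Adipocyte genes were called without click replicate 2 (-0.21, camera adjusted p = 0.0345), without click replicate 3 (-1.35, 0.0112) and without EDC replicate 3 (-0.49, 0.0487), and fatty acid oxidation genes without click replicate 3 (0.38, 0.0226) and without EDC replicate 2 (0.44, 0.00908). Lists called without a single library were also mast cell (-1.07 without click replicate 1), myofibroblast (-1.19) and antigen presentation genes (-0.75, both without click replicate 3), glycolysis (0.60 without EDC replicate 2) and denervation genes (-0.53 without EDC replicate 3). The sex-linked list had too few measured members for the test.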

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

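Of the tests in this part, those on slow fibre genes, on macrophage, giant cell and matrix genes and on the splits of libraries for single genes were chosen after the result was seen.

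Reads on lines without a gene name, which no comparison uses, summed to 181384 over the 6 libraries, with 642 lines above 3 reads. They are given because no gene can be named for them; they hold at most 0.0996% of a library.

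Slow fibre genes lay 2.90 higher in click on the log2 scale, a pattern that a larger share of muscle fibre RNA, or a piece of muscle richer in slow fibres, could give. A larger share of fibre RNA moves slow and fast fibre genes alike, and the tables argue against it as the whole cause: the slow score less the fast score was 1.11, 2.16 and 0.15 in click against -1.84, -1.49 and -0.09 in EDC, and the group means differed by 2.28, more than the range within either group. The slow fibre score ranged over 2.50 within the click group. This is below the 2.86 between the group means by less than the spread of the click libraries, so a piece of muscle that differs in fibre makeup cannot be told apart from an effect of the agent. The labels name no muscle or sampling site, and an effect of the agents on fibre type stays open as well.

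Macrophage, giant cell and matrix genes lay lower in click. Dilution of all RNA that does not come from fibres would lower endothelial markers as much as macrophage markers, but the macrophage less the endothelial score was 0.16, -2.75 and -0.28 in click against 0.84, 0.62 and 1.41 in EDC, and without click replicate 2 the means lay -1.01 apart, beyond the range within click (0.45) or EDC (0.79). With all libraries the click mean lay -1.96 from the EDC mean for macrophage and -2.91 for giant cell and lysosomal genes. Without click replicate 2 these distances shrank to -1.13 and -1.29, still beyond the ranges within a group (at most 0.93 and 0.99). That library thus carried part of the difference, and the values argue against it as the whole cause for these lists, with 2 click libraries left. For matrix genes the means lay -0.75 apart, within the EDC range of 0.80, and click replicate 3 (0.37) lay above EDC replicate 2 (0.29), so there click replicate 2 and an effect of the agent cannot be told apart. Fewer macrophages near the sampled muscle in click mice, or a sample taken farther from a treated site, may both give this, and neither was tested.

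The T and NK and the B and plasma cell scores were higher in click replicates 2 and 3 than in the other libraries, but not every member was: Il7r was lowest in click replicate 2 and Igkc highest in EDC replicate 1. Lymph node tissue in the piece would raise naive lymphocyte and follicle genes in both, and 75% of 12 did so (9 genes, 95% exact binomial interval 42.8% to 94.5%), with 4 of the 12 above 1 CPM in every EDC library. Activated lymphocytes would raise effector genes in both, and 33.3% of 12 did so (interval 9.92% to 65.1%); 2 of these 12 are above 1 CPM in every EDC library and 4 are in the T and NK list. The 2 intervals overlap, so these shares alone do not tell the 2 explanations apart. Of the 9 genes, S1pr1 counted by a narrow margin, at 30.97 CPM in click replicate 2 against 30.91 in EDC replicate 3. The effector genes Gzmb, Gzmk, Ifng, Cd40lg and Cxcr6 had 0 reads in click replicate 2, while 4 of the 12 were higher in both. The lymph node genes Glycam1 (605 and 1241 reads) and Cxcl13 (648 and 1156 reads) had 0 reads in click replicate 1 and at most 27 in an EDC library. Cr2 (151 and 312 reads) had 0 reads in the other libraries, and Fcer2a (260 and 959 reads) had at most 6. These single genes were chosen after their values were seen, so they do not decide between the 2 explanations. Most effector genes are low, so activated lymphocytes are not excluded. Other sources of lymphocytes were not tested.

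The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1 gene and the highest other split 1, and 2 of the 10 gave as many. For lists, the real split gave 22 and the highest other 24, in the split of click replicates 1 and 2 with EDC replicate 2 from the rest, and 2 of the 10 gave as many. That other split also gave more genes at an unadjusted edgeR p under 0.05, 2517 against 2404 in the real split. By DESeq2 the real split gave 606 genes and the highest other, the same split, 313.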

How the results depend on the processing

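Of these settings, the sex covariate, male libraries alone and the mt-Atp6 class covariate were chosen after the data were seen. With DESeq2 606 genes differed (247 higher, 359 lower in click). The edgeR count of 1 fell to 0 with the replicate block, the sex covariate, male libraries alone and the mt-Atp6 class covariate, where Gdpd3 had edgeR adjusted p of 0.0877, 0.107, 0.231 and 0.254, and limma-voom gave 0 (adjusted p 0.266). Over the alternatives the adjusted p of Gdpd3 ran from 4.01e-31 (DESeq2) to 0.372. It was called with the other scalings and filters, and its direction was kept in all settings. Leaving out 1 library gave 0 to 7 genes differing, 0 to 7 higher and 0 to 1 lower; without click replicate 1 they were 7, among them Gdpd3 and Ms4a1, without click replicate 3 Gdpd3 and Rsc1a1, and without EDC replicate 3 Rc3h2 alone. Lists called numbered 20 to 25 over scalings, filters, covariates and left-out libraries, and 0 with an estimated correlation or by fry's directional test (7 by its mixed test). Of those 7, only the pericyte list was among the 22. Same-numbered libraries correlated in their deviations at -0.05, 0.19 and 0.28. For click replicates 2 and 3 the same-numbered EDC library gave the highest value, and for click replicate 1 it did not. Pairing by number is thus neither shown nor excluded. With the replicate block 3673 genes had an unadjusted edgeR p under 0.05, against 2404 without it. The block called 24 lists, 21 of the 22 among them, without tendon (-1.46, camera adjusted p = 0.107). Log2 fold changes reversed with library totals for Myh4 (-0.25) and Tnnt3 (-0.069), as that scaling moved all genes by -0.48, and for Ypel3, which ranged from -0.56 to 0.074 as libraries were left out; the cause was not tested. Of the other values of named genes under alternatives, 1290 kept their direction and side of the threshold, 39 passed it and 9 no longer did. All 9 are of Gdpd3, the only gene past the threshold in the main test. The 1290 are mostly genes that were not called and stayed so, which is no sign of stable calls. Fewer libraries leave fewer residual degrees of freedom. Spread between libraries, not read depth, limits these tests.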

Other observations

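The genes in this part, and the line that parts the libraries by mt-Atp6 reads, were chosen after their values were seen.

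DESeq2 called 606 genes where edgeR called 1, and all 606 had an unadjusted edgeR p under 0.05, with 556 showing no overlap between the groups. These genes were picked for a difference in the same counts, so neither number is separate support for the calls. Among the fixed lists these calls fell on 10 of 12 slow fibre genes, 7 of 20 T and NK cell markers (Cd3g, Cd8a, Cd8b1, Trac, Trbc1, Trbc2 and Lck), 5 of 15 mitochondrially encoded genes and 4 of 14 Schwann cell and nerve markers, all higher in click by their fold change. Of these T cell genes only Cd8b1 had click values all above the EDC values. Trbc2 was at 1.19, 7.47 and 44.6 CPM in click replicates 1 to 3 and at 3.14 in EDC replicate 1. Lower in click were 8 of 21 macrophage markers, among them Adgre1 and Csf1r, 6 of 22 cytokine and chemokine genes, among them Ccl2, Ccl7 and Cxcl2, 5 of 12 neutrophil markers and 4 of 17 giant cell and lysosomal genes. DESeq2 called Hmox1, Mt1 and Mt2 lower among the oxidative stress genes, and Myh3 and Myl4, contractile genes of developing muscle, lower among the regeneration genes. In simulated data for this comparison the DESeq2 test made 48 false calls among 188.

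The acute phase gene Saa3 had 126, 0 and 163 reads in the click libraries and 3127, 89 and 21761 in the EDC libraries, and Mmp13 had 3290 reads in EDC replicate 3 and 259 or fewer elsewhere. Click replicate 2 had 0 reads of Saa3, Mmp12, Mmp13, Atp6v0d2 and Sfrp2, which had 18 or more in each other library. Immunoglobulin reads stood out in EDC replicate 1, with 11268 reads of Igkc and 4128 of Ighg1 against at most 3866 and 48 elsewhere.

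A set of genes parted click replicate 2 and EDC replicates 1 and 3 from the other 3 libraries, across the groups. The ratio of mt-Atp6 reads to reads of its nuclear copy Gm10925 was 0.937, 0.927 and 0.937 in the former and 0.162, 0.162 and 0.166 in the latter. Nek7 had 5391, 4472 and 4453 reads against 554, 703 and 503, and Sumo2 had 606, 732 and 1027 against 2199, 2216 and 2180. The neutrophil genes S100a9 and Retnlg also followed this line. The labels name no counting run, library batch or mouse line that matches it, and whether it comes from the counting or from the mice was not tested. The split of libraries along this line called 0 genes by edgeR (262 at an unadjusted p under 0.05) and 17 by DESeq2, with 5 lists by camera.

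Counts of a few genes were at 0 in some libraries of a group and high in others. Qser1 had 2930 reads in click replicate 3 and 0 in the other 5 libraries, and Kctd12 had 871, 430 and 0 reads in click and 0, 1781 and 4440 in EDC.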
